A study of Nicotiana tabacum with 12 samples.

How the data were processed

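Transcript levels were measured in leaves of tobacco (Nicotiana tabacum) on 12 one-colour Agilent tobacco arrays, each hybridised with Cy3-labelled cDNA from 1 sample. Per the labels, 3 arrays came from control plants carrying an empty vector, 3 from control plants given methyl jasmonate (MeJA), 3 from plants in which NtCOI1 was silenced by RNA interference, and 3 from silenced plants given MeJA. The labels call the 3 samples of a group biological replicates. MeJA-treated samples were harvested after 7 days of treatment per the descriptions, except replicate 3 of the MeJA-treated silenced group, whose description gives the untreated wording for the harvest. The descriptions of replicates 2 and 3 of both silenced groups name NtCOI2 and NtCOI3 as the silenced gene, whereas the titles and the tags name NtCOI1, and groups follow the titles.

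The deposited scanner files hold spot intensity values that, per the file headers, were made with Agilent Feature Extraction 11.5.1.1 and the protocol GE1_1105_Oct12, which subtracts background and gives a processed signal per spot. Each array held 45220 spots, of which 1417 were control spots. The authors also deposited a table of normalized signals of all arrays on a log2 scale and 4 tables of their own comparisons with a fold change as a ratio, a p-value and a corrected p-value per probe. The test and the correction behind those p-values are not given in the sources used here. The values of the log2 table had the same distribution in every column, the sorted values of any pair of columns differing by at most 0.0075 apart from the extreme ends of the distribution, so the table is quantile normalized. Its columns name groups and replicate numbers, and 24 of its per-sample columns, like 72 in the comparison tables, were not used.

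The columns of the log2 table could not be matched to the arrays of the scanner files. The rank correlation over 43664 probes between a table column and an array lay between 0.855 and 0.952 in all 144 pairs, while arrays of one group correlated at 0.975 to 0.991 and table columns of one group at 0.963 to 0.991. The table was therefore tied to groups only and used as an alternative source of values, never joined to an array.

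Control spots were left out, as were spots that the scanner software had called non-uniform or population outliers. These made up 0.0297% to 33.6% of the probe spots of an array (33.6% on replicate 3 of the MeJA-treated control group) and had a higher median signal than the other spots on all 12 arrays. Values were log2 processed signals minus the 75th percentile of each array. The percentile was taken over all probe spots, a choice made on seeing that the outlier calls fall on bright spots. Spots of one probe were averaged. A probe was tested when it was well above background on all arrays of at least 1 group, was listed in the deposited table and had at least 1 usable array in every group, which left 36996 of 43759 probes. A minimum of 2 usable arrays per group had been tried first and was lowered after its counts were seen, because it dropped bright probes and left 30411. Per array, 83.6% to 88.7% of probe spots were well above background and none was saturated.

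Each comparison was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 over all 12 arrays with 1 coefficient per group, and p-values were adjusted by the Benjamini-Hochberg method within a comparison, a probe counting as changed at an adjusted p under 0.05. The 4 comparisons named in the design text and the difference between the MeJA responses of silenced and control plants were fitted. Files were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. All values are relative to an array's own 75th percentile, so a change of total RNA per leaf would not be seen. On simulated arrays with independent normal noise of each probe's own spread and 200 changed probes among 36996, 16% of 2-fold and 94% of 8-fold changes were recovered for MeJA in control, 10% and 76% for silencing untreated, 6% and 66% for MeJA in silenced, 14% and 82% for silencing under MeJA, and 0% and 50% for the difference of responses. Each share rests on 50 simulated probes, so the shares do not rank the comparisons. Far more probes were called with MeJA than were changed in the simulation, so they do not give the sensitivity there.

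Names came from the annotation columns of the deposited tables, in which many probes carry the name of a similar gene of another species. Of 17778 accessions in the annotation 0 matched the reference gene table, no genome was used, and no coordinates are given. A gene was a UniGene cluster or, without one, a probe. The probe with the highest mean over the 12 arrays stood for it, which gave 29632 genes, 6900 of them with an informative name. Named genes were chosen by a rule fixed before the data were examined: NtCOI1, then the 10 largest rises and 10 largest falls among named genes past the test whose arrays did not overlap between the groups and that were well above background on all arrays of 1 of them, and up to 4 members of a discussed list with the smallest adjusted p. Overlap was judged on the values of all spots, outlier spots included, as decided after the files were read. The lists to discuss were picked after the list results had been seen. A probe not well above background on any array of a group has only a bound there, and its change is given as at least N-fold, the mean of the bright group over the mean, per array, of the higher of the lowest signal well above background and the probe's own.

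A set of 30 gene lists was fixed as name patterns before the data were examined, and 28 had at least 3 measured members. They were JA biosynthesis, JA signalling, COI1, nicotine synthesis and transport, polyamine and phenolamide synthesis, anti-herbivore proteins, pathogenesis-related proteins, phenylpropanoid and flavonoid synthesis, terpenoid synthesis, photosynthesis, senescence and chlorophyll breakdown, cell cycle and histones, cell wall, cytosolic ribosomal proteins, ethylene, gibberellin, auxin, abscisic acid and dehydration, heat shock proteins, oxidative stress, WRKY, MYB, AP2/ERF and NAC factors, and general reference genes. Markers of guard cells and epidermis, roots, and flowers and pollen stood for other cell types, with photosynthesis for mesophyll. Glandular trichome markers and phloem and xylem markers had fewer than 3 measured members and were not tested. Each list was tested with limma's camera with a preset correlation of 0.01 and adjusted over 140 tests. Camera with a correlation estimated from the arrays and fry were run beside it, both with outlier spots kept. List medians are given relative to the median of all genes. Camera asks whether a list changed more than the other genes, and fry whether it changed at all. A list counts as called by camera with the preset correlation unless another test is named. None of the 44 list calls held with an estimated correlation, a setting in which the spots used differ as well as the correlation. With outlier spots kept and the preset correlation, 43 of the 44 held. The 44 include the COI1 list in both silencing comparisons, which holds the silenced gene's own probes and is no separate finding.

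The 12 arrays lay on 3 slides of 4 positions. Slide 1 held the 3 control arrays and replicate 1 of the MeJA-treated control group, slide 2 the other MeJA-treated control arrays and silenced replicates 1 and 2, and slide 3 silenced replicate 3 and the 3 MeJA-treated silenced arrays. The MeJA comparisons were therefore repeated within slide 1 and within slide 3, and all comparisons with the slide as a block. For the MeJA comparisons this block gives in effect the same estimate as the slide alone, so the 2 are not separate checks. The 2 groups of a silencing comparison share no slide, so neither silencing comparison can be repeated within one. With the slide as a block, some coefficients could not be estimated for probes with few usable spots. Alternatives fixed before the data were examined were quantile normalization, the authors' table, no filter on dim probes and a stricter one, only the 2 groups compared, the replicate number or the slide as a block, an intensity trend, array weights and leaving out each array. A background correction planned on mean signals fell back on quantile normalization alone, because the deposited files hold no mean-signal column. Alternatives added after seeing the data were normexp with an offset of 50 on median signals with quantile normalization, outlier spots kept, the 75th percentile over the other spots only, and at least 2 usable arrays per group.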

Results

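Leaf transcripts of tobacco were measured in 4 groups of 3 samples, made of control plants with an empty vector and plants with NtCOI1 silenced by RNA interference, each untreated and given methyl jasmonate (MeJA). COI1 is the F-box receptor of the hormone jasmonate (JA), and MeJA is taken up and turned into JA. Each array gave 43759 probes, of whose spots 83.6% to 88.7% were well above background, with a median processed signal of 522 to 922 intensity units. Arrays of one group correlated across probes at a rank correlation of 0.975 to 0.991, and arrays of different groups at 0.919 to 0.979. The number of arrays limits the precision.

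The arrays of the groups were spread unevenly over 3 slides, and the silenced and control arrays of each silencing comparison shared no slide. The columns of the authors' deposited table of normalized signals could not be matched to the scanner files, since the rank correlation between any of its columns and any array was at most 0.952 in 144 pairs. Values below come from the scanner files unless the table is named. Across probes, the log2 changes in the table correlated with those of the scanner files at 0.40 for MeJA in control, 0.06 for silencing untreated, 0.60 for MeJA in silenced and 0.15 for silencing under MeJA.

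NtCOI1 transcript was lower in silenced than in control plants by 2 of the 3 probes annotated as COI1, called NtCOI1 probes here. The gene rule counts these 3 probes as separate genes, so whether all of them read NtCOI1 is open. Probe A_95_P219532 read −1.20 ± 0.26 (log2 relative to the array's 75th percentile, SD, n = 6) in silenced and 0.25 ± 0.25 (n = 6) in control arrays, a 2.72-fold lower level. Probe A_95_P239539 read −0.79 ± 0.30 and 0.23 ± 0.27 (SD, n = 6 each), 2.03-fold lower. For both, every silenced array lay below every control array, and an exact two-sided permutation test over 924 splits gave p = 0.00216, the smallest it can give. Probe A_95_P094878 read −0.33 lower, with an exact permutation p = 0.184. The place of the probes relative to the silencing fragment is not in the files, so a probe inside it would also read the construct.

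Within each treatment, limma gave NtCOI1 changes of −1.37 (adjusted p = 0.0155) and −0.9999 (adjusted p = 0.0457) without MeJA and of −1.51 (adjusted p = 0.0040) and −1.04 (adjusted p = 0.0218) with MeJA for probes A_95_P219532 and A_95_P239539. The NtCOI1 probe A_95_P094878 gave −0.59 (adjusted p = 0.213) and −0.063 (adjusted p = 0.935). MeJA itself left the 3 NtCOI1 probes short of the test in control plants, at 0.42, 0.39 and 0.14. In the authors' deposited comparison of these groups A_95_P219532 went the other way, 1.77-fold lower with MeJA (corrected p = 0.0272). A slide block gave NtCOI1 changes of −1.22 (adjusted p = 0.846) and −0.53 (adjusted p = 0.882) without MeJA and −1.34 (adjusted p = 0.403) and −0.62 (adjusted p = 0.739) with it, so no call held. Slide 2 holds control MeJA replicates 2 and 3 and untreated silenced replicates 1 and 2. On it A_95_P219532 read 0.47 and 0.37 in control against −1.01 and −1.57 in silenced arrays. A_95_P239539 read 0.38 and 0.21 against −0.67 and −1.07. These arrays differ in MeJA as well as in silencing. The call of A_95_P219532 without MeJA was lost without control replicate 2 (adjusted p = 0.0601), silenced replicate 2 (0.0697) or silenced replicate 3 (0.0708). The call of A_95_P239539 without MeJA was lost without control replicate 2 (adjusted p = 0.160), control MeJA replicate 3 (0.0520), silenced replicate 1 (0.0625), 2 (0.163) or 3 (0.121), or silenced MeJA replicate 1 (0.0716), 2 (0.0665) or 3 (0.0513). Its call under MeJA was lost without control MeJA replicate 1 (adjusted p = 0.0638), silenced MeJA replicate 1 (0.0719) or silenced MeJA replicate 3 (0.0652). In the authors' deposited comparison tables the NtCOI1 folds were 3.34, 1.98 and 2.58 lower without MeJA (corrected p = 0.259, 0.328 and 0.258) and 2.16, 1.63 and 1.12 lower with it (corrected p = 0.00751, 0.0105 and 0.632).

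**Figure D1:**
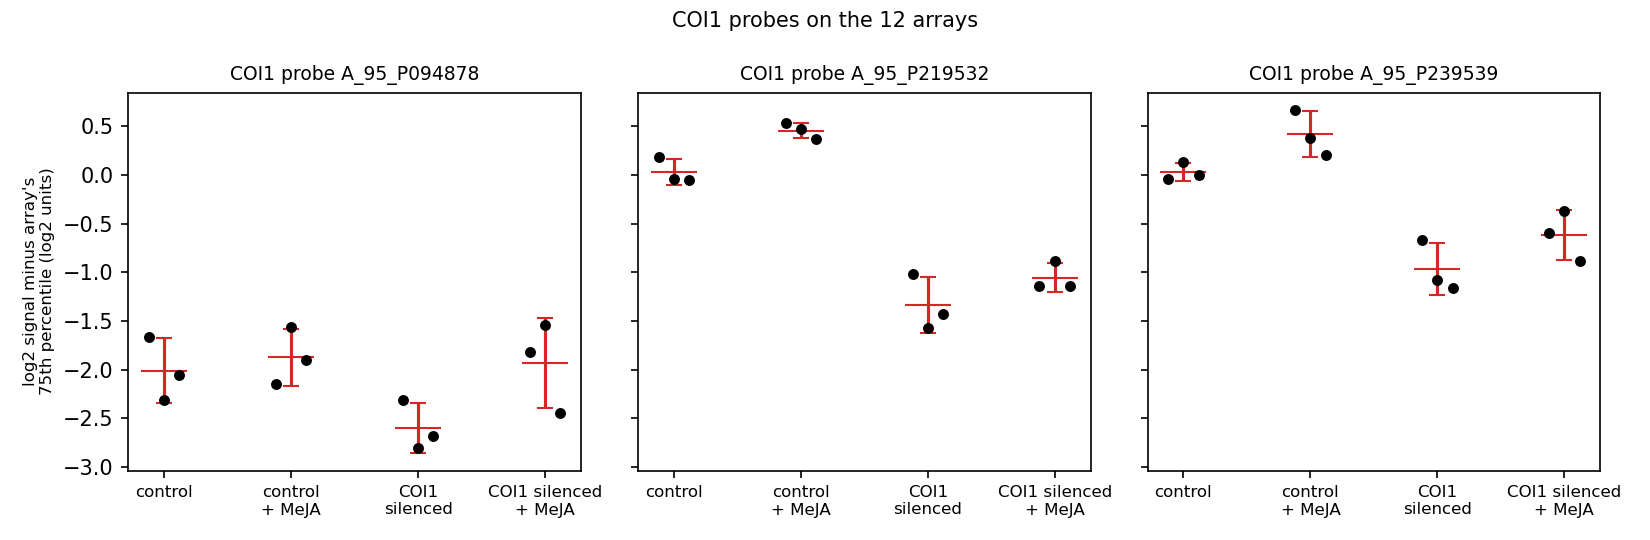
Level of the 3 NtCOI1 probes on each of the 12 arrays by group, as log2 signal relative to the array's 75th percentile, with group means and SD. For probes A_95_P219532 and A_95_P239539 the highest silenced array (−0.88 and −0.37) lay below the lowest control array (−0.050 and −0.037).

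MeJA treatment of control plants for 7 days asks which leaf transcripts respond to the hormone when its receptor is present. Among the largest rises, TPS21 (A_95_P259126), named after a caryophyllene synthase of sesquiterpene defence, rose by 5.73 log2 units (SE 1.34, adjusted p = 0.0152, limma), and an epi-aristolochene synthase, the first enzyme of the phytoalexin capsidiol, by 5.52 (SE 1.31, adjusted p = 0.0159). NTSQUA4 (A_95_P009246), a MADS-box transcription factor, rose from −9.23 ± 1.17 to −2.96 ± 0.88 (SD, n = 3 each), with 1 of the 3 control arrays well above background. The terpenoid list was not called, with 1 higher and 4 lower of 23 (camera adjusted p = 0.477). NtJAZ1 (A_95_P077670), a repressor that the COI1 receptor sends to degradation and whose gene JA induces, rose by 1.98 (SE 0.23, adjusted p = 0.00171) and NtJAZ3 (A_95_P234579) by 1.34 (SE 0.27, adjusted p = 0.0139). The largest fall was bobTIP26-1, a water channel of the vacuole membrane, at −6.88 (SE 0.84, adjusted p = 0.00102), and a chlorophyll a/b-binding protein of the light-harvesting antenna fell by 4.89 (SE 0.50, adjusted p = 0.0015).

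The other largest rises with MeJA in control plants were PAR-1a (7.62, n = 2 usable arrays in each group), the ammonium transporter AMT1;2 (6.37), a cytochrome P450-like gene (5.53), a cytochrome P450 (A_95_P289933, 5.40), the zinc finger gene ZFP16-1 (5.19) and an acyltransferase-like gene (5.19). An anthranilate N-hydroxycinnamoyl/benzoyltransferase gene rose at least 8.97-fold. The other largest falls were a TIP aquaporin (A_95_P015251, −6.48), a GDSL lipase (−5.96), a replacement histone H4 (−5.92), GAMMA-TIP (−5.83), a non-specific lipid-transfer protein (−5.28), delta-TIP (−5.22), a beta-1,3-glucanase-like protein (−5.22) and an H3 histone (−5.20). Of the genes named for this comparison, AMT1;2 and ATNAC2 had 1 usable MeJA array and histone H4 and NtJAZ3 1 usable control array, so their spread comes largely from the other groups. The epi-aristolochene synthase, the P450 gene A_95_P289933 and the acyltransferase-like gene were well above background on 1 of 3 control arrays, and the glucanase-like gene on 1 of 3 MeJA arrays, so their changes start or end mostly at background. In all, 7794 of 36996 probes changed, 3872 higher and 3922 lower, of which 5313 by at least 2-fold, and 13682 had an unadjusted p under 0.05. By gene, 3138 were higher and 3075 lower. The authors' deposited comparison gave 15116 of 34701 probes with a corrected p under 0.05, 8010 higher and 7106 lower. The slide block left 1287 probes called, and within slide 1 (3 control arrays and 1 MeJA array) limma called 0 of 36984, with 6155 at an unadjusted p under 0.05. Both estimates rest on that single MeJA array, which within slide 1 is assumed to vary like the control arrays. Their log2 changes are in effect the same, so a match between them is no separate check. The log2 changes within slide 1 correlated across probes with those from all arrays at 0.916, and all 42 genes named for this comparison kept their sign there, though these arrays are part of both fits. The largest rises and falls were picked for arrays that did not overlap between the groups, which fixes their sign within a slide. The count was 4424 without control replicate 2 and 4674 without control MeJA replicate 2, and without control replicate 3 the calls were 5007 higher and 3317 lower.

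Photosynthesis genes were lower as a list with MeJA in control plants: of 78 measured, 0 were higher and 31 lower (44 lower adjusted over the list alone), with a median of −0.97 relative to all genes. The camera test gave adjusted p = 1.05e-13 with the preset correlation and adjusted p = 0.458 with an estimated correlation, which ends the call, and the median was −0.82 both within slide 1 and with the slide as a block. Its antenna precursor (A_95_P022336) fell by 4.13 (SE 0.47, adjusted p = 0.00105) and the photosystem I subunit PSI-E B by 1.97. Cell cycle and histone genes numbered 25 lower and 0 higher of 71 (29 lower adjusted over the list alone), led by a cyclin A-like gene (−3.26), histone HTA7 (−3.88) and NtH4 (−2.43). Their median was −0.78, with camera adjusted p = 9.86e-09 and adjusted p = 0.365 with an estimated correlation, and −0.67 within slide 1 and with the slide as a block. Cell wall genes numbered 30 lower and 1 higher of 106 (34 lower and 3 higher adjusted over the list alone), among them a pectate lyase (A_95_P144922, at least 2.22-fold lower), a polygalacturonase-like gene (−1.58) and a polygalacturonase inhibitor (−2.47). Their median was −0.78, with camera adjusted p = 3.82e-06 and adjusted p = 0.46 with an estimated correlation, and −0.9998 within slide 1 and with the slide as a block. Ribosomal protein genes numbered 76 lower and 2 higher of 277 (90 lower and 2 higher adjusted over the list alone), with RPL9 at −1.56 (SE 0.19, adjusted p = 0.00105), RPS9 at −2.17 and L38 at −1.09. Their median was −0.53, with camera adjusted p = 1.87e-11 and adjusted p = 0.392 with an estimated correlation, and −0.50 within slide 1 and with the slide as a block.

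WRKY, NAC and MYB genes were higher as lists with MeJA in control plants with the preset correlation and not with an estimated correlation (adjusted p = 0.484, 0.365 and 0.501), while AP2/ERF genes, with 3 of 24 higher, were short of the test (camera adjusted p = 0.0504). A MYB gene (A_95_P196562) rose by 4.39 (SE 0.24, adjusted p = 9.16e-05) and MYB123 by 3.63 (SE 0.26, adjusted p = 0.00029), WRKY2 by 1.12, CaWRKY1 by 2.36, ATNAC2 by 1.94 and a NAC gene (A_95_P293863) by 1.15. WRKY genes numbered 7 higher and 0 lower of 22 (7 higher and 1 lower adjusted over the list alone), with a median of 0.97, camera adjusted p = 0.000698 and adjusted p = 0.484 with an estimated correlation. NAC genes numbered 6 higher and 0 lower of 12 (6 and 0 adjusted over the list alone), with a median of 0.57, camera adjusted p = 0.0303, and adjusted p = 0.365 with an estimated correlation. MYB genes numbered 6 higher and 2 lower of 25 (6 and 2 adjusted over the list alone), with a median of 0.32, camera adjusted p = 0.0105, and adjusted p = 0.501 with an estimated correlation. Abscisic acid and dehydration genes numbered 9 higher and 2 lower of 37 (10 and 3 adjusted over the list alone). They were led by the carotenoid dioxygenases NCED4 (1.96, SE 0.20, adjusted p = 0.000762) and CCD1 (0.98). Both are in the list by name, and their rise does not show more abscisic acid synthesis. In the authors' table both were lower (−3.51 and −1.14), and camera did not call the list (adjusted p = 0.971). In the scanner files the median of the list was 0.32, with camera adjusted p = 0.0204 and adjusted p = 0.365 with an estimated correlation. Within slide 1 and with the slide as a block the WRKY, NAC, MYB and abscisic acid medians were 1.43, 0.81, 0.27 and 0.41. Pathogenesis-related genes numbered 3 higher and 10 lower of 52 (3 and 10 adjusted over the list alone), with a median of −0.23 (0.0251 with quantile normalization and 0.0432 with the strict filter on dim probes), camera adjusted p = 0.0464, adjusted p = 0.534 with an estimated correlation, and a median of −0.40 within slide 1 and with the slide as a block. In the authors' table their median was 0.887, with 24 higher and 11 lower.

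JA biosynthesis genes were not called as a list by camera with MeJA in control plants, 1 of 18 being higher and 1 lower, but were past the test by fry (adjusted p = 0.0188). Nor were JA signalling genes called, with 2 of 7 higher and 1 lower. The lower one, an outward rectifying potassium channel (−1.44, adjusted p = 0.0472), is in that list by its description and is not known as a JA gene. Nicotine genes, whose root-made product defends the leaf, gave 1 higher and 1 lower of 19. In the authors' deposited table, JA biosynthesis had 12 genes higher and nicotine synthesis 12, and camera called both lists higher (adjusted p = 0.00289 and 0.0165). Among cell type markers, guard cell and epidermis genes gave 1 higher and 2 lower of 15, root genes 4 higher of 16, and flower and pollen genes 8 higher and 3 lower of 41, none called as a list by camera, beside the photosynthesis list above. Root genes were past the test by fry (adjusted p = 0.0335). In the authors' table guard cell and epidermis genes were called lower by camera, with 9 lower of 15 (adjusted p = 0.000138). Of the 42 genes named for MeJA in control plants, 11 had the opposite sign in the authors' deposited table: both P450 genes, bobTIP26-1, GAMMA-TIP, the lipid-transfer protein, PSI-E B, the pectate lyase, the polygalacturonase inhibitor, ATNAC2, NCED4 and CCD1. A slide block left 23 of the 42 called, and 38 were called without any 1 array.

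Silencing NtCOI1 in untreated leaves asks which transcripts need the receptor without added hormone. Among the largest falls, the putative metallocarboxypeptidase inhibitor genes NtMCPIb (A_95_P005196) and NtMCPIa, whose kind of protein blocks gut enzymes of insects, fell by 3.71 (SE 0.34, adjusted p = 0.0125) and 5.22 (SE 0.34, adjusted p = 0.0267). NtMCPIa had 1 usable array in each group, so its spread comes from the other groups alone. Nictaba (A_95_P026141), a JA-induced leaf lectin, fell from 1.88 ± 1.61 to −3.08 ± 0.28 (SD, n = 3 each). NtJAZ1 fell by 2.24 (SE 0.21, adjusted p = 0.0125) and NtJAZ2 (A_95_P242737) by 2.49 (SE 0.33, adjusted p = 0.0272). The largest rises were a polysaccharide biosynthesis gene (at least 3.76-fold) and sulfate transporter 2, which imports sulfate, at 2.65 (SE 0.46, adjusted p = 0.0402).

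The other largest falls on silencing in untreated leaves were phnC (−3.50), heat shock transcription factor 1 (−3.44), RS2 (−3.17), cysteine-rich extensin-like protein-4 (−3.17), Cig1 (−3.10), a glycosyl hydrolase of family 3 (at least 1.36-fold) and a tumor-related protein (−2.71). The other largest rises were a 101 kDa heat shock protein (2.21), a methyltransferase (2.16), a disease resistance protein (2.04), a chalcone and stilbene synthase family gene (2.02), a NAC gene (A_95_P257584, 1.96), the annexin ann12 (1.88), FRS4 (1.88) and an ATP synthase beta subunit (1.84). The methyltransferase had 1 usable silenced array. Pathogenesis-related genes were not called as a list, with 3 lower of 52 (camera adjusted p = 0.0847). In all, 400 of 36996 probes changed, 200 higher and 200 lower, of which 377 by at least 2-fold, and 8863 had an unadjusted p under 0.05. By gene, 166 were higher and 164 lower. The groups share no slide, and with the slide as a block limma called 1 probe, with 2075 at an unadjusted p under 0.05, and 0 of the 26 genes named for this comparison, which kept their sign, 17 of them with a smaller change. With the replicate number as a block 14 probes were called. The count was 1092 without control replicate 1, 19 without control replicate 2, 3477 without control replicate 3 (2809 higher and 668 lower), 1014 without control MeJA replicate 1 (347 and 667) and 737 without control MeJA replicate 2. It was 69 without silenced replicate 1, 0 without silenced replicate 2, 0 without silenced replicate 3, and 81, 80 and 254 without silenced MeJA replicates 1, 2 and 3, all by limma. None of the 26 named genes was called without every single array in turn, and the authors' deposited comparison gave 0 of 34251 probes with a corrected p under 0.05, with 5091 at an uncorrected p under 0.05.

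JA signalling genes were lower as a list on silencing in untreated leaves, with 2 lower and 0 higher of 7 (3 lower adjusted over the list alone), a median of −0.79, camera adjusted p = 1.70e-06, and adjusted p = 0.365 with an estimated correlation. The COI1 list (3 probes, 2 lower, 2 adjusted over the list alone) gave camera adjusted p = 3.69e-05, and adjusted p = 0.365 with an estimated correlation. This list holds only the probes annotated as the silenced gene, so its call repeats their single results and is no separate finding. Their estimated correlation was 0.567, against the preset 0.01. Nicotine genes had a median of −0.66, with 0 of 19 past the test (1 higher and 3 lower adjusted over the list alone), camera adjusted p = 0.00109, and adjusted p = 0.365 with an estimated correlation. Anti-herbivore genes had a median of −0.87, with 1 of 19 lower, a Kunitz protease inhibitor at −1.36 (4 lower adjusted over the list alone), camera adjusted p = 0.00906, and adjusted p = 0.365 with an estimated correlation. Phenylpropanoid and flavonoid genes had a median of −0.46, with 1 of 46 lower, the flavanone 3-hydroxylase NtF3H at −2.004 (2 lower adjusted over the list alone), camera adjusted p = 0.00138, and adjusted p = 0.365 with an estimated correlation. Cell wall genes had a median of −0.43, with 4 of 106 lower (6 adjusted over the list alone), among them pectate lyases P59 (−1.24) and Nt59 (−1.40), camera adjusted p = 3.69e-05, and adjusted p = 0.484 with an estimated correlation. Polyamine genes had a median of −0.29, with 0 of 14 past the test (1 lower adjusted over the list alone), camera adjusted p = 0.0266, and adjusted p = 0.501 with an estimated correlation. The JA signalling, COI1, nicotine, anti-herbivore, phenylpropanoid, cell wall and polyamine medians with the slide as a block were −0.88, −1.07, −0.49, −0.80, −0.25, −0.49 and −0.35.

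WRKY genes, regulators of defence, were higher as a list on silencing in untreated leaves, with a median of 0.89, 0 of 22 past the test and 9 higher adjusted over the list alone, camera adjusted p = 4.35e-05, and adjusted p = 0.419 with an estimated correlation. Ribosomal protein genes had a median of −0.38, with 0 of 277 past the test and 0 adjusted over the list alone, camera adjusted p = 9.15e-13, and adjusted p = 0.392 with an estimated correlation. Cell cycle genes had a median of −0.34, with 0 of 71 past the test and 0 adjusted over the list alone, camera adjusted p = 0.000473, and adjusted p = 0.498 with an estimated correlation. Oxidative stress genes had a median of −0.19, with 0 of 118 past the test and 0 adjusted over the list alone, camera adjusted p = 0.0225, and adjusted p = 0.501 with an estimated correlation. General reference genes had a median of −0.25, with 1 of 64 lower (3 adjusted over the list alone), camera adjusted p = 0.00814, and adjusted p = 0.365 with an estimated correlation. Among cell type markers, guard cell and epidermis genes had a median of −0.55, with 0 of 15 past the test and 0 adjusted over the list alone, camera adjusted p = 0.0149, and adjusted p = 0.365 with an estimated correlation. Photosynthesis (78), root (16) and flower and pollen genes (41) had 0 past the test by limma and were not called as lists. With the slide as a block the WRKY, ribosomal, cell cycle, oxidative stress, reference and guard cell medians were 1.49, −0.44, −0.21, −0.19, −0.32 and −0.49, and the oxidative stress call was lost (camera adjusted p = 0.0954). In the authors' deposited table the WRKY, ribosomal, cell cycle, cell wall and reference medians had the opposite sign, as had 8 of the 26 named genes: the 101 kDa heat shock protein, the disease resistance protein, the NAC gene, ann12, RS2, the glycosyl hydrolase and both pectate lyases. Camera with the preset correlation called the ribosomal (0.297, adjusted p = 2.49e-18) and cell cycle lists (0.207, adjusted p = 0.00479) higher in that table.

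MeJA treatment of silenced plants asks which transcripts still respond to the hormone when its receptor is low. CP1 (A_95_P214812), a cysteine protease named for leaf senescence, rose at least 222-fold (adjusted p = 0.000329). Cig1 (A_95_P010646) rose by 6.69 (SE 0.59, adjusted p = 0.000414) and NTSQUA4 by 6.54 (SE 0.71, adjusted p = 0.000511). Apyrase 3, whose kind of enzyme breaks down nucleotides, fell from 1.02 ± 0.66 to −5.11 ± 0.59 (SD, n = 3 each), and a polyphenol oxidase, which makes leaf protein less digestible to insects, fell by 6.37 (SE 0.80, adjusted p = 0.000791). NtJAZ1 still rose, by 1.31 (SE 0.19, adjusted p = 0.00273), as did the related TIFY8 (1.31, SE 0.35, adjusted p = 0.0235).

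The other largest rises with MeJA in silenced plants were DREB3 (5.88), TPS21 (5.70), the epi-aristolochene synthase (5.58), a gene named only as a transcription factor (A_95_P191007, 4.98), the cytochrome P450 A_95_P289933 (4.78), the glycosyltransferase NtGT5a (4.78) and a zinc-binding oxidoreductase (4.70). The other largest falls were the lipid-transfer protein (−7.05), a germin-like protein (−6.95), the chlorophyll a/b-binding protein (−6.76), a proline-rich protein (−6.65), the GDSL lipase (−6.20), cysteine-rich extensin-like protein-2 (−5.95), a xyloglucan transferase (−5.86) and bobTIP26-1 (−5.73). DREB3 had 1 usable array in each group, so its spread comes from the other groups alone, the chlorophyll a/b-binding protein had 1 usable untreated array, and the lipid-transfer protein was well above background on 1 of 3 MeJA arrays. In all, 7463 probes changed, 2853 higher and 4610 lower, of which 5187 by at least 2-fold, and 12531 had an unadjusted p under 0.05. By gene, 2286 were higher and 3644 lower. The authors' deposited comparison gave 19053 of 34259 probes with a corrected p under 0.05, and more of them were higher (10658) than lower (8395). With the slide as a block 2226 probes were called. Within slide 3 (1 untreated and 3 MeJA arrays) 2744 of 34704 were called, with the spread taken from the 3 MeJA arrays alone and the single untreated array assumed to vary like them, and the slide block rests on the same untreated array. There the log2 changes correlated across probes with those from all arrays at 0.963, and 37 of 37 named genes with a value kept their sign, though these arrays are part of both fits. The lack of overlap asked of the largest rises and falls fixes their sign within a slide. The count was 4557 without silenced replicate 1, 4115 without silenced replicate 3, 4815 without silenced MeJA replicate 1 and 4832 without silenced MeJA replicate 2.

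Photosynthesis genes were lower as a list with MeJA in silenced plants, with 43 lower and 0 higher of 78 (52 lower adjusted over the list alone), the antenna precursor at −3.22 and a plastocyanin-like gene at −1.41. Their median was −1.03, with camera adjusted p = 2.33e-13 and adjusted p = 0.458 with an estimated correlation. Cell wall genes numbered 48 lower and 7 higher of 106 (57 and 11 adjusted over the list alone), with fasciclin-like arabinogalactan protein 10 at −4.28 (SE 0.46, adjusted p = 0.000498) and an arabinogalactan protein (A_95_P002686) at −4.71. Their median was −1.22, with camera adjusted p = 1.18e-09 and adjusted p = 0.392 with an estimated correlation. Cell cycle genes numbered 17 lower and 2 higher of 71 (17 and 2 adjusted over the list alone), with a median of −0.40, camera adjusted p = 0.00804, and adjusted p = 0.58 with an estimated correlation. Anti-herbivore genes numbered 9 lower and 3 higher of 19 (11 and 3 adjusted over the list alone), with a polyphenol oxidase (A_95_P218517) at −6.08, chloroplast threonine deaminase 1 at −1.25 and arginase 2 at 1.44. Their median was −0.97, with camera adjusted p = 0.0225 and adjusted p = 0.416 with an estimated correlation, and −0.87 with MeJA in control plants, where 1 was higher and 2 lower and the list was not called (camera adjusted p = 0.187). Within slide 3 the photosynthesis, cell wall, cell cycle and anti-herbivore medians were −1.26, −1.21, −0.32 and −0.89, and with the slide as a block −1.24, −1.19, −0.34 and −0.88.

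Phenylpropanoid and flavonoid genes, which make lignin units and pigments, numbered 11 higher and 1 lower of 46 with MeJA in silenced plants (11 and 1 adjusted over the list alone). Caffeoyl-CoA O-methyltransferase 3 rose by 3.93 (SE 0.63, adjusted p = 0.00241), flavonol synthase by 1.98 and cinnamoyl-CoA reductase by 1.75. The median was 0.34, with camera adjusted p = 0.00112 and adjusted p = 0.365 with an estimated correlation. With MeJA in control plants this list had 9 higher and 1 lower, short of the test by camera (adjusted p = 0.114) and past it by fry (adjusted p = 0.00473). JA signalling genes numbered 4 higher and 0 lower of 7 (4 and 0 adjusted over the list alone), with a median of 0.71, camera adjusted p = 0.0428, and adjusted p = 0.539 with an estimated correlation. WRKY genes numbered 8 higher and 0 lower of 22 (8 and 0 adjusted over the list alone), with WRKY2 at 0.89 and NtWRKY-7 at 0.96, a median of 0.93, camera adjusted p = 0.00109, and adjusted p = 0.46 with an estimated correlation. NAC genes numbered 4 higher and 0 lower of 12 (5 and 0 adjusted over the list alone), with ATNAC2 at 2.36 and anac036 at 2.18, a median of 0.70, camera adjusted p = 0.011, and adjusted p = 0.365 with an estimated correlation. MYB genes numbered 4 higher and 1 lower of 25 (4 and 1 adjusted over the list alone), with a median of 0.16, camera adjusted p = 0.0303, and adjusted p = 0.533 with an estimated correlation. AP2/ERF genes numbered 4 higher and 0 lower of 24 (2 and 0 adjusted over the list alone), with a median of 0.32, camera adjusted p = 0.0303, and adjusted p = 0.501 with an estimated correlation. Within slide 3 the phenylpropanoid, JA signalling, WRKY, NAC, MYB and AP2/ERF medians were 0.31, 0.67, 1.05, 0.72, 0.12 and 0.29, and with the slide as a block 0.31, 0.68, 0.91, 0.63, 0.11 and 0.34. The slide block ended the calls of JA signalling (camera adjusted p = 0.107) and AP2/ERF (0.133), and the replicate number as a block those of JA signalling (0.0539) and MYB (0.0578).

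Abscisic acid genes were not called as a list with MeJA in silenced plants, with 5 higher and 2 lower of 37 (camera adjusted p = 0.122). JA biosynthesis genes were not called by camera there either, with 4 lower of 18. Among them were fatty acid hydroperoxide lyase (−2.33, SE 0.29, adjusted p = 0.000783) and a lipoxygenase (A_95_P150967, −1.64). The lyase is in that list by its name and is not known as a JA synthesis enzyme. Ribosomal protein genes numbered 27 lower and 2 higher of 277, not called as a list. Among cell type markers, guard cell and epidermis genes gave 3 lower of 15, root genes 3 higher of 16, and flower and pollen genes 8 higher and 3 lower of 41, none called as a list by camera, beside the photosynthesis list above. Of the 38 genes named for this comparison, 6 had the opposite sign in the authors' deposited table: the transcription factor A_95_P191007, the lipid-transfer protein, bobTIP26-1, threonine deaminase, flavonol synthase and NtWRKY-7. The phenylpropanoid median was −0.155 there. A slide block left 25 of the 38 called, and 34 were called without any 1 array.

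Silencing under MeJA asks which transcripts differ between silenced and control plants once the hormone is given. Apyrase 3 was lower by 7.08 (SE 0.50, adjusted p = 0.00128), at −5.11 ± 0.59 in silenced against 1.96 ± 0.52 in control plants (SD, n = 3 each). A polyphenol oxidase was lower by 6.42 (SE 0.73, adjusted p = 0.00384) and asparagine synthetase, which stores nitrogen as asparagine, by 4.50 (SE 0.35, adjusted p = 0.0015). The JA repressor genes NtJAZ1, NtJAZ2 and NtJAZ3 were lower by 2.92 (SE 0.21, adjusted p = 0.00248), 2.40 (SE 0.46, adjusted p = 0.0334) and 1.18 (SE 0.20, adjusted p = 0.0263). The largest rise was a cysteine peptidase (A_95_P242647), 5.88 higher (SE 0.82, adjusted p = 0.00716), with CP1 4.51 higher (SE 0.81, adjusted p = 0.0207). The cysteine peptidase, the f-box gene and TGA10 were well above background on 1 of 3 control arrays, and NtJAZ2 had 1 usable control array.

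The other largest falls on silencing under MeJA were cysteine-rich extensin-like protein-3 (−5.94), heat shock transcription factor 1 (−5.69), Nictaba (−4.83), BYJ15 (−4.50), NtMCPIa (−4.24, 1 usable control array), a glycine-rich protein (−3.95) and a polygalacturonase subunit (−3.94). The other largest rises were patatin-like protein 1 (4.84), ACRE132 (4.55), an f-box family gene (3.63), the transcription factor A_95_P191007 (3.57), LRR2 (at least 7.88-fold), NtEIG-E80 (3.34), TGA10 (3.06) and ACRE74 (3.01). In all, 1133 probes changed, 271 higher and 862 lower, of which 1005 by at least 2-fold, and 7025 had an unadjusted p under 0.05. By gene, 229 were higher and 664 lower. The groups share no slide, and with the slide as a block limma called 0 probes, with 2924 at an unadjusted p under 0.05, and 0 of the 33 genes named for this comparison, which kept their sign, 11 of them with a smaller change. With the replicate number as a block 630 probes were called. The count was 748, 2825 (1627 higher and 1198 lower) and 415 without control MeJA replicates 1, 2 and 3, and 394, 475 and 710 without silenced MeJA replicates 1, 2 and 3, and 16 of the 33 genes were called without any 1 array. The authors' deposited comparison gave 10041 of 33197 probes that had a corrected p under 0.05, 5715 higher and 4326 lower.

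JA biosynthesis genes were lower as a list on silencing under MeJA, with 2 lower of 18 (5 adjusted over the list alone). The 2 were a lipoxygenase (A_95_P029636, −3.18, SE 0.40, adjusted p = 0.00509) and hydroperoxide lyase (−2.12). Hydroperoxide lyase is in that list by its name and is not known as a JA synthesis enzyme. The median of the list was −0.32, with camera adjusted p = 0.00109 and adjusted p = 0.365 with an estimated correlation. JA signalling genes numbered 3 lower of 7 (4 adjusted over the list alone), with a median of −0.55, camera adjusted p = 3.82e-06, and adjusted p = 0.365 with an estimated correlation. The COI1 list (2 lower of 3, 2 adjusted over the list alone) gave camera adjusted p = 0.000204, and adjusted p = 0.392 with an estimated correlation, again repeating the single probes of the silenced gene. Anti-herbivore genes numbered 4 lower of 19 (8 lower and 1 higher adjusted over the list alone), with threonine deaminase at −1.66, a median of −0.88, camera adjusted p = 5.25e-05, and adjusted p = 0.365 with an estimated correlation. Cell wall genes numbered 22 lower of 106 (39 lower and 5 higher adjusted over the list alone), with expansin Nt-EXPA2 at −2.19, fasciclin-like protein 10 at −3.06 and FLA8 at −3.76. Their median was −0.73, with camera adjusted p = 1.18e-09 and adjusted p = 0.365 with an estimated correlation. WRKY genes numbered 1 higher of 22 (3 adjusted over the list alone), NtEIG-D48 at 0.95, with a median of 0.90, camera adjusted p = 5.56e-05, and adjusted p = 0.392 with an estimated correlation. General reference genes numbered 1 lower of 64 (7 adjusted over the list alone), with a median of −0.22, camera adjusted p = 0.0303, and adjusted p = 0.365 with an estimated correlation. With the slide as a block the JA biosynthesis, JA signalling, COI1, anti-herbivore, cell wall, WRKY and reference medians were −0.39, −0.56, −0.66, −0.66, −0.76, 0.73 and −0.33.

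Nicotine genes were not called as a list on silencing under MeJA, with 1 of 19 lower, A622L at −0.89 (SE 0.19, adjusted p = 0.0322), while 14 were lower in the authors' deposited table. Phenylpropanoid genes gave 1 higher and 2 lower of 46, with chalcone synthase at −2.32 and a rhamnosyltransferase-like gene at 1.78. Among cell type markers, guard cell and epidermis genes had a median of −0.45, with 0 of 15 past the test and 0 adjusted over the list alone, camera adjusted p = 0.0428, and adjusted p = 0.392 with an estimated correlation. The guard cell median was −0.44 with the slide as a block. Photosynthesis genes gave 1 lower of 78, root genes 0 of 16 by limma, and flower and pollen genes 4 lower of 41, none called as a list. In the authors' deposited table the cell wall and reference medians had the opposite sign (0.238 and 0.312), as had 7 of the 33 named genes: the f-box gene, TGA10, ACRE74, threonine deaminase, fasciclin-like protein 10, FLA8 and the rhamnosyltransferase-like gene. Camera with the preset correlation called the cell wall and reference lists higher in that table (adjusted p = 0.0441 and 0.00423).

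**Figure D2:**
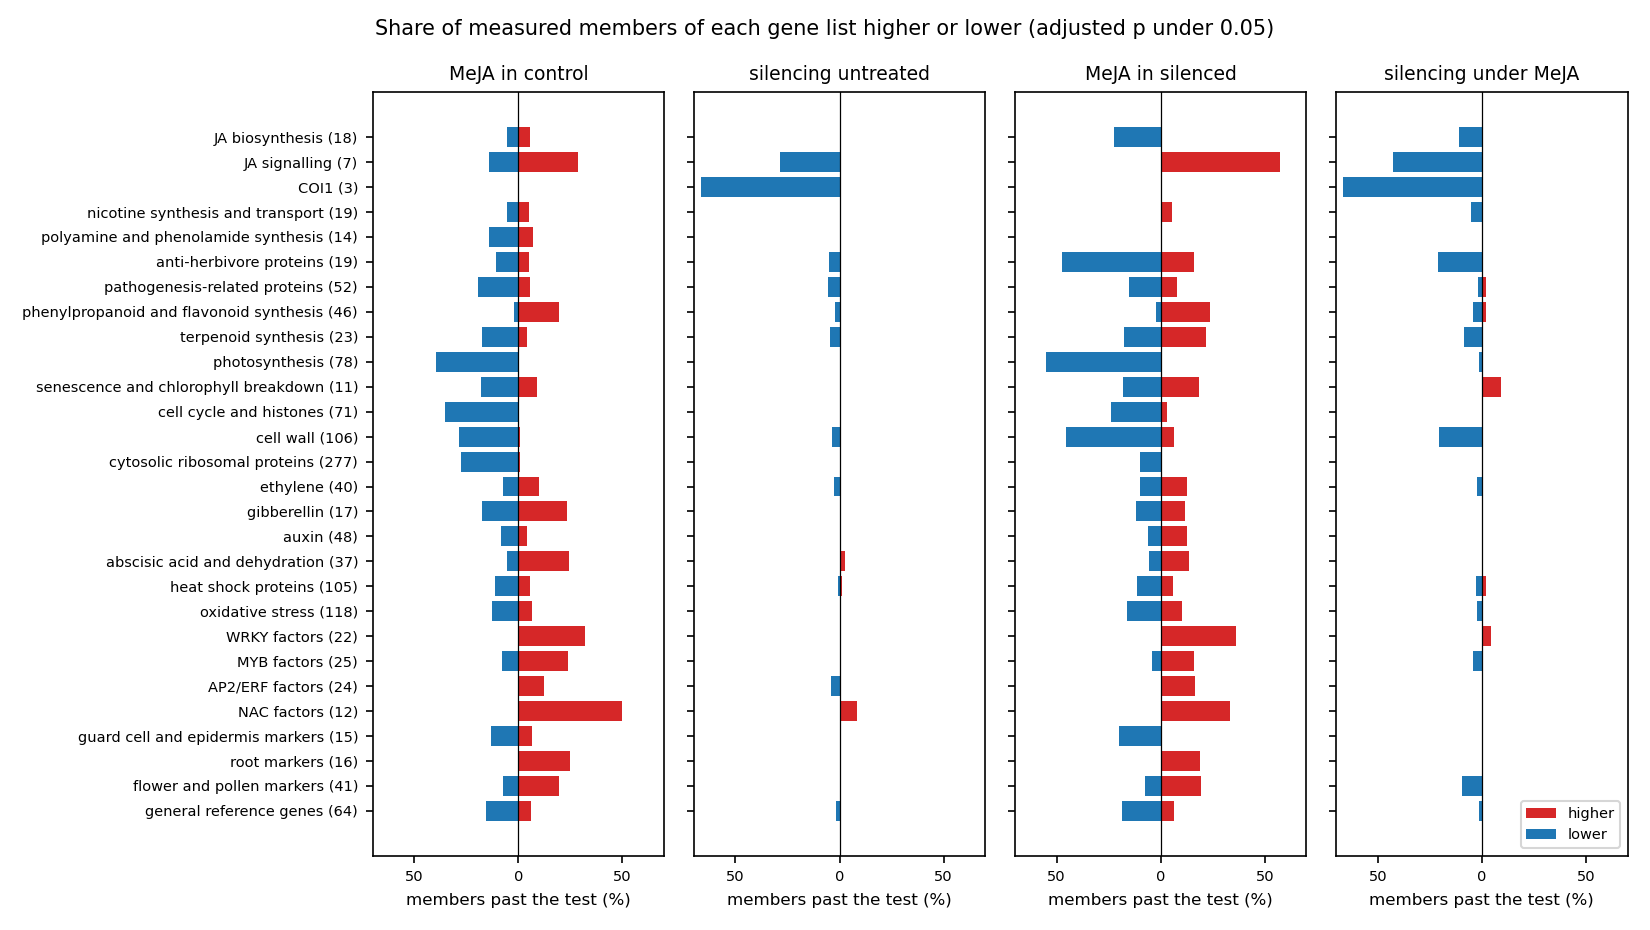
Share of the measured members of each gene list that were higher or lower past the test, in the 4 comparisons. Photosynthesis had 31 and 43 of 78 genes lower with MeJA in control and silenced plants, and JA signalling 2 and 3 of 7 lower on silencing without and with MeJA.

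The response to MeJA was also compared between silenced and control plants, which asks whether low NtCOI1 changes it. For 0 of 36996 probes did the responses differ past the test by limma, and 4947 had an unadjusted p under 0.05. The authors' table gave 3986 for this difference, 2258 higher and 1728 lower. NtJAZ1 rose in both (1.98 and 1.31), as did NTSQUA4 (6.26 and 6.54), and the chlorophyll a/b-binding protein fell in both (−4.89 and −6.76). Across probes, which are not independent replicates, the responses correlated at r = 0.661 (rho 0.564, slope 0.671), with 1444 probes higher in both, 2446 lower in both and 28 called in opposite directions. Lists of these sizes drawn independently would share 299 and 489. Silencing without and with MeJA correlated at r = 0.460 (rho 0.376), with 18 probes higher in both and 71 lower in both against 1.47 and 4.66 for independent lists. All these comparisons take each probe's spread from the same fit, which by itself favours calling the same probes. Both silencing comparisons also set later slides against earlier ones, so a slide difference could raise their overlap and correlation. The counts for independent lists therefore cannot show that an overlap comes from MeJA or silencing. The correlation of MeJA responses with the slide as a block was 0.614 and limma called 0 probes, with 1655 at an unadjusted p under 0.05. The count of the difference was 5 without control replicate 1, 534 without control replicate 3, 249 without control MeJA replicate 1, 45 without control MeJA replicate 2, 1 without silenced MeJA replicate 2 and 4 without silenced MeJA replicate 3. By list, JA biosynthesis had a median difference of −0.38 relative to all genes for 18 genes (0 past the test by limma, 0 adjusted over the list alone), with camera adjusted p = 0.0343 and adjusted p = 0.365 with an estimated correlation. This list was not called by camera in either plant, with 1 higher and 1 lower in control and 4 lower in silenced, and the difference was short of the test with the slide (camera adjusted p = 0.0545) or the replicate number (0.051) as a block. Pathogenesis-related, cell cycle and ribosomal genes differed the other way, at medians of 0.515, 0.322 and 0.352 (2, 0 and 0 higher adjusted over the list alone, limma), with camera adjusted p = 0.0018, 0.000695 and 1.42e-09 and adjusted p = 0.365, 0.484 and 0.432 with an estimated correlation. Guard cell, root, flower and pollen, and photosynthesis markers were not called for the difference. Lists called by camera with the preset correlation in the authors' table, where no estimated correlation was run, included nicotine (median −1.93, 4 lower of 19, adjusted p = 1.08e-06), phenylpropanoid (−0.757, 9 lower of 46, adjusted p = 7.66e-08), heat shock (0.492, 36 higher and 1 lower of 105, adjusted p = 9.06e-10) and JA biosynthesis genes (−0.32, 5 lower of 18, adjusted p = 1.55e-05). Nicotine, phenylpropanoid and heat shock genes were not called for the difference in the scanner files, at medians of 0.456, 0.101 and 0.0326.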

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

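The tests on the authors' normalization, on mislabelled columns, on the sign in the authors' table and on other splits of the samples were chosen after the results they measure were seen, and the other tests were planned before.

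The camera test put 4 gene lists past the threshold for the difference between the MeJA responses of silenced and control plants, which is a difference between groups. JA biosynthesis (18 genes) had a median difference of −0.38 log2 relative to all genes, with camera adjusted p = 0.0343 and adjusted p = 0.365 with an estimated correlation, and 0 genes past the test over the list alone. Its adjusted p was 0.0545 with the slide as a block and 0.051 with the replicate number as a block, and its median in the authors' table was −0.32. Pathogenesis-related proteins (52 genes) had a median of 0.515, with camera adjusted p = 0.0018 and adjusted p = 0.365 with an estimated correlation, 2 genes being higher adjusted over the list alone. Cell cycle and histone genes (71) had a median of 0.322, with camera adjusted p = 0.000695 and adjusted p = 0.484 with an estimated correlation, and 0 genes past the test over the list alone. Cytosolic ribosomal protein genes (277) had a median of 0.352, with camera adjusted p = 1.42e-09 and adjusted p = 0.432 with an estimated correlation, and 0 genes past the test over the list alone. With the slide as a block the last 3 medians were 0.82, 0.27 and 0.30, and the authors' table gave 0.19, −0.126 and 0.25. For single probes limma called 0 of 36996 for this difference, with 4947 at an unadjusted p under 0.05.

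The 6 arrays of each comparison make 10 splits into groups of 3, too few for a share under 0.05. In each of the 4 comparisons 1 of the 10 splits, the real one, called as many probes. The real split and the highest other gave 7794 and 30 for MeJA in control, 400 and 30 for silencing untreated, 7463 and 0 for MeJA in silenced, and 1133 and 529 for silencing under MeJA, all by limma. The split with 529 put MeJA control replicates 1 and 3 with MeJA silenced replicate 1, which leaves MeJA control replicate 2 on the silenced side. For the difference of MeJA responses the real grouping gave 0, a count that every split reaches, so 100 of 100 splits gave as many. The highest other gave 3414, in a split whose 2 added groups held 5 of the MeJA-treated arrays, while other drawn splits with 5 such arrays gave 0 or 1. Shuffled groups mix the effects of MeJA and silencing into the difference, so these counts cannot tell whether the samples hold another structure. The 3 drawn splits that kept the MeJA-treated silenced arrays, which share slide 3, together as a group gave 3414, 510 and 19, and the other drawn splits at most 3, while the real grouping, which also keeps them together, gave 0 by limma, with 4947 at an unadjusted p under 0.05.

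The authors' table and the scanner files ordered the probes differently. A normalization that keeps the order of probes would leave a rank correlation near 1 between a column and its array, and the highest of any column with any array was 0.952. Columns mislabelled among the 12 arrays would leave such a match in another group, where the highest value was also 0.952. Noise of dim probes does not account for it either, since over the 17192 brightest probes the highest value was 0.831, against a lowest of 0.899 between arrays of one group. The table may therefore come from other hybridisations of such samples, a source that could not be tested, and no biological explanation was tested.

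The rises of silencing under MeJA (271 probes, median 2.10) were set against the authors' table, where 58.3% had the same sign against 52.8% of all probes and 35 were called the same way and 18 the opposite way. These rises may therefore be limited to the scanner arrays. The untreated silenced array of slide 3 differed from those of slide 2 by a median of −0.275 in the direction of these calls, but this rests on a single array and leaves a difference of slide 3 open. As a biological source, genes that MeJA lowers in control plants made up 8.12% of these probes in the authors' table against 22.02% of all. Since that table hardly reproduces these rises, the share cannot decide this source.

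The falls of silencing under MeJA (862 probes, median −1.70) had the same sign in the authors' table for 64.3% against 47.2% of all probes, and 294 were called the same way and 94 the opposite way, which argues against a pattern of the scanner arrays alone. Genes that MeJA raises in control plants made up 19.6% of them in the authors' table against 27.4% of all. Log2 changes in the table correlated with those of the scanner files at 0.40 for MeJA in control and 0.15 for silencing under MeJA. The share therefore cannot decide this biological source. The slide test gave −0.017 in the direction of these calls, and for silencing untreated it gave 0.0567 for the 200 rises (median 1.66; 50.5% with the same sign in the authors' table against 53.003% of all) and 0.261 for the 200 falls (median −1.81; 66.0% against 47.0%). Each rests on a single array on 1 side, and no slide holds both groups of a silencing comparison, so the slide block reaches silencing only through arrays of another group. With it 1132 of the 1133 calls under MeJA kept their sign and the log2 changes correlated with the reported ones at 0.870, on many of the same arrays, so a slide effect is neither shown nor excluded and could lie behind part of the calls.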

How the results depend on the processing

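The alternatives chosen after the results were seen were normexp on median signals, outlier spots kept, the percentile over the other spots only, and at least 2 usable arrays per group; the other tests were planned before. For every value below that differs from the report, the cause was not tested unless a construction is named. The signal over background, above the limit for 83.6% to 88.7% of spots per array, limits which dim probes can be tested.

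The authors' table gave 18291 probes for MeJA in control, 19997 for MeJA in silenced (11023 higher and 8974 lower), 9527 for silencing under MeJA (5436 and 4091) and 3986 for the difference (2258 and 1728), and 471 for silencing untreated. The 139 named genes count a gene once in each comparison that names it, so some genes are counted more than once. Of these 139, 72 kept their call there, 35 kept only their sign and 32 reversed. The correlation of MeJA responses was 0.805 there. NtCOI1 probes A_95_P219532 and A_95_P239539 read −0.82 and −0.50 with MeJA in control, −0.19 and −0.22 with MeJA in silenced, and 0.63 and 0.28 for the difference. Of these only the −0.82 was past the test by limma (adjusted p = 0.00256). Without MeJA, silencing gave −1.37 for A_95_P094878, past the test (adjusted p = 0.0246), and −0.99 for A_95_P239539, short of it (adjusted p = 0.0583).

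Named genes reversed in the authors' table with MeJA in control were a P450-like gene (−2.85), a P450 (−1.48), bobTIP26-1 (0.19), GAMMA-TIP (0.33), the lipid-transfer protein (4.08), PSI-E B (1.66), a pectate lyase (0.043), a polygalacturonase inhibitor (0.23), ATNAC2 (−0.41), NCED4 (−3.51) and CCD1 (−1.14). For silencing untreated they were the 101 kDa heat shock protein (−0.72), the disease resistance protein (−0.19), a NAC gene (−0.078), ann12 (−2.12), RS2 (0.59), the glycosyl hydrolase (0.22), P59 (0.018) and Nt59 (0.86). For MeJA in silenced they were the transcription factor A_95_P191007 (−2.34), the lipid-transfer protein (1.58), bobTIP26-1 (0.27), threonine deaminase (1.30), flavonol synthase (−2.91) and NtWRKY-7 (−0.99). For silencing under MeJA they were the f-box gene (−0.15), TGA10 (−0.48), ACRE74 (−0.46), threonine deaminase (0.074), fasciclin-like protein 10 (0.74), FLA8 (0.29) and the rhamnosyltransferase-like gene (−0.22).

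Of the 44 list calls, 18 held in the authors' table, 14 kept camera's direction short of the threshold and 12 reversed. The reversed medians were pathogenesis-related 0.887 (MeJA in control), cell cycle 0.207, cell wall 0.0688, ribosomal 0.297, WRKY −0.233 and reference 0.05004 (silencing untreated), phenylpropanoid −0.155 (MeJA in silenced), cell wall 0.238 and reference 0.312 (silencing under MeJA), and cell cycle −0.126 (difference). Ribosomal and cell cycle genes on silencing untreated were past the threshold in that reversed direction. So were cell wall and reference genes on silencing under MeJA. JA signalling with MeJA in silenced (0.0775) and guard cell genes on silencing under MeJA (−0.0040) kept the sign of the median and reversed in camera's direction. Short of the threshold in the authors' table were ribosomal (−0.128), abscisic acid (0.161) and MYB (0.360) with MeJA in control, nicotine (−0.439), polyamine (−0.0821), phenylpropanoid (−0.111), oxidative stress (−0.0299) and guard cell genes (−0.163) on silencing untreated, anti-herbivore (−0.0399), MYB (−0.0322, the opposite sign of the reported median) and NAC genes (0.813) with MeJA in silenced, COI1 (−0.732) and WRKY genes (0.0018) on silencing under MeJA, and pathogenesis-related genes (0.186) for the difference. Calls lost elsewhere kept camera's direction: 9 of 44 under fry, 7 with quantile normalization, 7 with normexp, 7 with the percentile over the other spots, 6 with the strict filter, 9 with at least 2 usable arrays, 4 with the slide and 3 with the replicate number as a block, 3 with array weights, 3 with all probes, 1 with the trend and 1 with outlier spots kept. Pathogenesis-related genes with MeJA in control were lost with quantile normalization (0.0251), normexp and the strict filter (0.0432), so the sign of that median is not stable. Fry lost polyamine, cell cycle, cell wall and oxidative stress genes on silencing untreated, JA signalling and AP2/ERF with MeJA in silenced, and pathogenesis-related, cell cycle and ribosomal genes for the difference.

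The slide as a block gave 1287 probes for MeJA in control, 1 for silencing untreated, 2226 for MeJA in silenced, 0 for silencing under MeJA and 0 for the difference by limma, with 8526, 2075, 8791, 2924 and 1655 at an unadjusted p under 0.05. It left 48 of the 139 named genes and gave 8 cell type marker calls in place of 4. NtCOI1 read −1.22 and −0.53 without MeJA and −1.34 and −0.62 with it for A_95_P219532 and A_95_P239539, all short of the test, and A_95_P094878 read −0.14 with MeJA in control. By construction this setting rests on the few arrays that share a slide. The replicate number as a block gave 5179, 14, 5703 and 630 probes in the same order and 0 for the difference, by limma, with 4249 at an unadjusted p under 0.05, and kept 96 of the 139 genes. NtCOI1 without MeJA fell short there at −1.37 (adjusted p = 0.0613) and −0.9999 (adjusted p = 0.0892). The numbers pair no samples in this block, as changes of arrays with the same number correlated at only −0.245 to 0.0869.

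Quantile normalization gave 7891, 912, 8062 and 1257 probes and 13 for the difference, and normexp 8021, 965, 8466 and 1284 (486 higher and 798 lower) and 27. NtCOI1 probe A_95_P094878 read −0.016 with MeJA in control under quantile normalization and, on silencing under MeJA, 0.019 with quantile normalization, 0.049 with normexp and 0.090 with array weights, while A_95_P239539 read 0.19 for the difference with normexp. Array weights gave 6822, 3456 (2414 higher and 1042 lower), 11333 and 1660 probes and 9 for the difference, and the intensity trend 8534, 521, 8287 and 1254, and 8. No filter on dim probes gave 7154, 247, 6909 and 957, the strict filter 7677, 481, 7505 and 1147. With no filter NtCOI1 probe A_95_P239539 read −0.9999 without MeJA (adjusted p = 0.0525). Only the 2 groups compared, whose spread comes from their 6 arrays alone, gave 2504, 326 (92 higher and 234 lower), 8852 and 392 (162 and 230), with A_95_P239539 at −0.9999 (adjusted p = 0.0671) without and −1.04 (adjusted p = 0.0811) with MeJA.

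Outlier spots kept gave 10520, 561, 10167 and 1817 probes, 1 for the difference and 7 marker calls. The percentile over the other spots only shifted the median of all genes by 0.091, 0.11, −0.18, −0.16 and −0.28 and gave 4206 (2537 higher and 1669 lower), 245 (151 and 94), 4430 (1241 and 3189) and 564 probes, 3 for the difference and 2 marker calls. NtCOI1 read −1.25 (adjusted p = 0.0858) and −0.87 (adjusted p = 0.170) without MeJA there and −1.32 (adjusted p = 0.0595) for A_95_P239539 with it. At least 2 usable arrays gave 7235, 460, 6811 and 1172 of 30411 probes. With an estimated correlation camera called 0 of the 44 lists and 0 of the 4 marker lists, and with all probes of a list 7 marker lists. Over these alternatives the adjusted p of NtCOI1 ran from 0.00661 to 0.846 and 0.0262 to 0.882 without MeJA, and from 0.0014 to 0.403 and 0.0133 to 0.739 with it.

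Leaving out 1 array gave 4424 to 8324 probes for MeJA in control, 0 to 3477 for silencing untreated, 4115 to 8185 for MeJA in silenced, 394 to 2825 for silencing under MeJA and 0 to 534 for the difference, by limma. The lowest counts came without control replicate 2 (4424), silenced replicate 2 (0) or 3 (0), silenced replicate 3 (4115) and MeJA silenced replicate 1 (394), and the highest without control replicate 3 (8324, 3477, 8185 and 534) and MeJA control replicate 2 (2825). The balance of higher and lower calls moved most without control replicate 3 (2809 and 668 for silencing untreated, 5007 and 3317 for MeJA in control) and without MeJA control replicate 2 (1627 and 1198 for silencing under MeJA). Named genes kept ran from 101 to 135. NtCOI1 ran from −1.53 to −1.26 and −1.15 to −0.90 without MeJA, and from −1.60 to −1.47 and −1.16 to −0.91 with it, for A_95_P219532 and A_95_P239539. A_95_P094878 ran from −0.26 to 0.19 on silencing under MeJA and from −0.015 to 0.31 with MeJA in control. For the difference A_95_P219532 ran from −0.26 to 0.022 and A_95_P239539 from −0.16 to 0.11. The correlations ran from 0.603 to 0.696 for MeJA and 0.344 to 0.509 for silencing. Leaving out an array reversed none of the 139 named genes past the test, an outcome that the rule of no overlap fixed for the largest rises and falls.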

Other observations

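The tests in this part were planned, except that the comparison of single arrays was chosen after the results were seen.

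Some planned gene lists were not called by camera in any comparison of the scanner files. Terpenoid genes (23) gave 1 higher and 4 lower with MeJA in control, 0 and 1 on silencing untreated, 5 and 4 with MeJA in silenced, and 0 and 2 on silencing under MeJA. In the same order, senescence genes (11) gave 1 and 2, 0 and 0, 2 and 2, and 1 and 0, ethylene genes (40) 4 and 3, 0 and 1, 5 and 4, and 0 and 1, and gibberellin genes (17) 4 and 3, 0 and 0, 2 and 2, and 0 and 0. Auxin genes (48) gave 2 and 4, 0 and 0, 6 and 3, and 0 and 0, and heat shock genes (105) 6 and 12, 1 and 1, 6 and 12, and 2 and 3. In the authors' table, camera with the preset correlation called ethylene genes higher with MeJA in control (21 and 1, adjusted p = 0.00666). It called heat shock genes lower there (24 and 50, adjusted p = 6.72e-06). In the scanner files camera called oxidative stress and polyamine genes as lists only on silencing untreated. With MeJA in control, in silenced and on silencing under MeJA, oxidative stress genes (118) gave 8 and 15, 12 and 19, and 0 and 3, and polyamine genes (14) 1 and 2, 0 and 0, and 0 and 0. AP2/ERF genes (24) gave 3 and 0 with MeJA in control, at camera adjusted p = 0.0504. All counts are from limma.

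Replicate 2 of the MeJA-treated control group correlated at 0.975 to 0.979 with the MeJA-treated silenced arrays and at 0.976 to 0.977 with its own group. Its NtCOI1 level was 0.47 and 0.38 by probes A_95_P219532 and A_95_P239539, among the control arrays.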
